A study of Mus musculus with 3 samples.

How the data were processed

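RNA was measured on 3 Affymetrix Mouse Genome 430 2.0 arrays, each hybridized with biotin-labelled cRNA from whole bone marrow of a mouse with leukemia driven by the MLL-AF6 fusion gene, delivered by a retrovirus. Per the labels, marrow cells were taken from terminally ill mice and received no treatment, and the series design adds that they were thawed before Trizol and column extraction. The 3 samples carry different animal codes and the replicate numbers 1, 2 and 3, and they form 1 group. That each came from a separate primary animal is read from these codes and is not spelled out. No array of normal marrow or of another leukemia was analysed here, so levels are described within this leukemia and the 3 arrays are compared with each other.

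The deposited values are intensities on a linear scale, and their nearly equal quantiles on the 3 arrays show that the authors had normalized them between arrays. RMA (robust multi-array average, which corrects background, equalizes the distribution of probe signals and summarises probes by median polish) is named in the submitters' processing notes without a version, and how linear values came from it is not given in the sources used here. The table holds 45101 probe sets per array, with medians of 29.5, 29.3 and 29.4 in replicates 1, 2 and 3 and maxima of 26720, 27258 and 22770. For 10483 probe sets (23.2%) the deposited value is identical on all 3 arrays. Values also recur within an array, with 19631, 19336 and 19647 distinct values in replicates 1, 2 and 3. The cause of these ties is not given in the sources used here, and an SD of 0 for such a probe set is not a measure of precision. Some tied values lie above the background level set below, such as Mllt1 at 6.72 log2 units on every array. Counts of genes above background, and of genes that did not vary, include them. There are no detection calls in the table, and the number of arrays limits the precision of every value.

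The values were log2-transformed (the floor of 1 changed no value). Probe sets were named through the platform annotation, which lists 35890 of them: 34958 with 1 gene and 932 with several. The other 9211 are unnamed here. Gene identifiers were updated through the RefSeq table of assembly GRCm38.p6, where 34754 of the single-gene probe sets matched and 204 kept the annotation's symbol. After the 64 array controls were set aside, 34945 single-gene probe sets represented 18193 genes. Each gene was represented by its probe set with the highest mean. List members described as not above background on any array had no single-gene probe set above it. No genome coordinates are given, because the deposited table names no build; the RefSeq table was used for names and for the order of neighbouring genes.

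Background was set on each array at the 95th percentile of 129 probe sets of olfactory, vomeronasal and taste receptors, keratin-associated proteins and protamines, which gave 5.36, 5.23 and 5.33 in log2 intensity for replicates 1, 2 and 3. A gene was called varying when its highest and lowest values differed by at least 1 log2 unit, and set apart in a replicate when that replicate lay at least 1 log2 unit above, or below, each of the other 2. Both counts were taken over genes above background on at least 1 array. Folds compare the replicate with the mean of the other 2 in log2. Where the low side was not above background, its background level took its place and the fold is written as "at least". Probe sets differ in how well they hybridize, so values are compared between arrays and never between genes.

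With 1 array per animal there are 0 residual degrees of freedom for a difference between animals, so no p-value is given, and statements rest on sizes, on the SD over 3 arrays and on agreement between probe sets. Of 29 gene lists fixed before the data were examined, 24 had at least 5 members above background. For each of these and each replicate, the median difference from the mean of the other 2 arrays was placed among 10000 random lists of the same size, matched on mean expression in 10 bins. A list was called set apart below percentile 1 or above percentile 99. These percentiles describe these 3 arrays. After the values were seen, the list shifts were also taken with every value below its array's background level raised to that level. Of 417 list entries, 368 were measured by a single-gene probe set.

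The named genes followed a rule also fixed before the data were examined. It takes every measured member of the MLL-fusion target, Hox and MLL and DOT1L complex lists, and the first 4 members plus up to 4 with the largest range in the other lists. It adds the 8 genes farthest above and below in each replicate and the 10 with the largest range, leaving out predicted gene models. A scan of neighbouring genes was added after the values were seen: the median difference was taken in windows of 25 genes above background on all 3 arrays and set against 1000 permuted gene orders.

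The procedures were tested on simulated arrays with a noise SD of 0.22, taken from pairs of probe sets of the same gene. Those pairs were above background on all arrays and were compared in their difference between replicates 1 and 2, the most alike arrays. In the simulation of genes set apart in replicate 3, over 10562 genes, 90.0% of genes changed by 1.5 log2 units and 100% of those changed by 3 were recovered, with 0 calls among 10362 unchanged genes. Noise this small rarely gives a gap of 1 log2 unit. The 0 calls therefore do not measure false calls among genes near background or under larger noise in replicate 3. Of 200 unshifted lists, 2 were called set apart, and of 50 lists shifted by 0.5 all 50 were. For the neighbour scan the noise SD was doubled to 0.43, and in a run of 60 neighbouring genes lowered by 0.8, 46 were recovered among 9574 genes. The alternatives were a stricter background (99th percentile), the mean of a gene's probe sets, median centring, lowess scaling, a threshold of 1.5, no background filter, means or unmatched random lists for the list shifts, and leaving out each replicate. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.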

Results

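Gene expression was profiled in whole bone marrow from 3 mice that had become terminally ill with leukemia driven by MLL-AF6, a fusion of the histone methyltransferase gene MLL (Kmt2a) with AF6 (Afdn) that is found in human acute leukemia. One array was run per sample. Of 18193 genes, 9574 lay above background on all 3 arrays, 511 on 2, 477 on 1 and 7631 on none. Replicates 1 and 2 resembled each other more than either resembled replicate 3. Over all probe sets other than controls, Pearson's r was 0.991 between replicates 1 and 2 (Spearman's rho 0.992), 0.969 between 1 and 3 (rho 0.975) and 0.972 between 2 and 3 (rho 0.975). These are correlations across probe sets, which are not independent replicates. The SD of the log2 difference was 0.32, 0.59 and 0.57 for the same pairs. Xist, the RNA that silences an X chromosome in female cells, stood at 12.94 ± 0.19 (SD, n = 3), and the Y-linked genes Eif2s3y, Kdm5d and Uty were not above background on any array.

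The first question was whether the genes known to be driven by MLL fusions were present in each leukemia. Hoxa9, the homeobox gene most closely tied to MLL-fusion leukemia, stood at 12.01, 11.63 and 11.23 log2 units in replicates 1, 2 and 3 (mean 11.62 ± 0.39 SD, n = 3, Entrez gene 15405). Its cofactor Meis1 stood at 9.41 ± 0.36, Hoxa10 at 9.18 ± 0.63, Hoxa7 at 7.97 ± 0.37 and Hoxa5 at 9.36 ± 0.71 (SD, n = 3). All 17 measured members of the MLL-fusion target list were above background on at least 1 array, and 14 on all 3. The proto-oncogene Myb (12.70 ± 0.28), the cell cycle kinase Cdk6 (11.79 ± 0.25), Lmo2 (11.59 ± 0.43), Jmjd1c (9.81 ± 0.35) and Cbx5 (8.86 ± 0.06) varied by less than 1 log2 unit between the leukemias. In all, 9 of the 17 varied by at least 1, among them Hoxa5 (range 1.38), Mef2c (1.29), Hoxa10 (1.18) and Hmgb3 (1.12).

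The 3 members not above background on every array separated replicate 3 from the rest. Mecom, which encodes the zinc finger transcription factor EVI1, was at 10.63 and 10.70 in replicates 1 and 2 and at 3.79 in replicate 3, where it was not above background (at least 40.4-fold lower, Entrez gene 14013). The remaining Mecom probe sets were not above background on any array, so this difference rests on 1 probe set. Eya1, a transcriptional coactivator and phosphatase, showed the opposite pattern, at 4.30, 4.30 and 9.52 (at least 18.7-fold higher in replicate 3), and so did Pbx3, a Hox cofactor, at 4.57, 3.56 and 8.37 (at least 8.40-fold higher). For Eya1 and for Pbx3 every probe set was highest in replicate 3. Among the members above background on all arrays, Zeb2 was 2.61-fold higher and Id2, an inhibitor of helix-loop-helix factors, was 4.22-fold lower in replicate 3. As a whole, the list lay at a median of -0.33 in replicate 3 against the other 2 (percentile 0.72 of random lists), with 7 members higher and 10 lower. Without replicate 2 that median was -0.09 (percentile 7.14 of random lists), inside the range of random lists. In replicate 1 the list median was 0.23 (percentile 99.82), with 10 members higher and 7 lower, a call also lost without replicate 2.

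**Figure D1:**
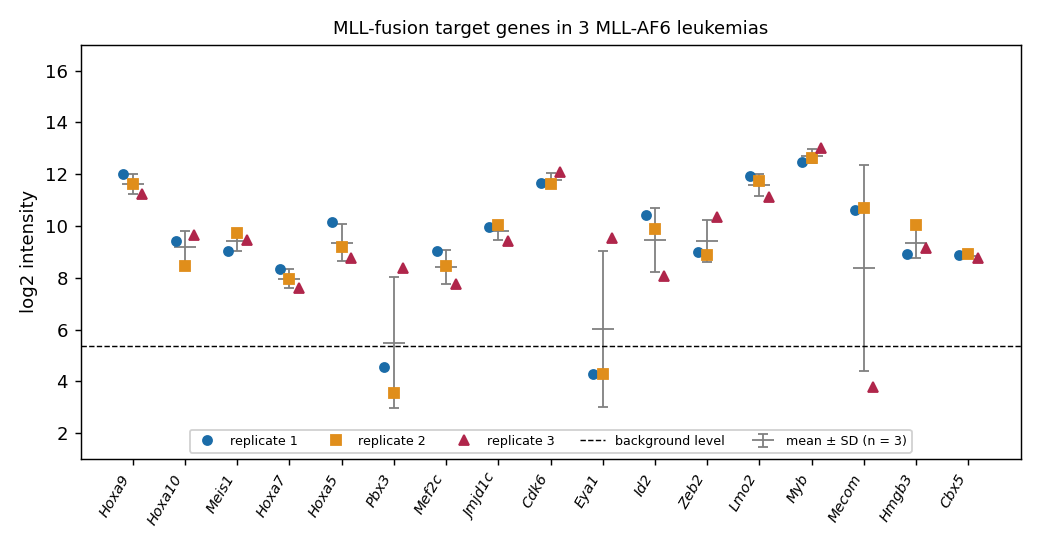
Log2 intensity (vertical axis) of the 17 measured MLL-fusion target genes (horizontal axis) in replicates 1, 2 and 3; grey bars are the mean ± SD over 3 arrays and the dashed line is the highest of the 3 background levels. Mecom lies at 10.63 and 10.70 in replicates 1 and 2 and at 3.79 in replicate 3, while Eya1 and Pbx3 are above the line in replicate 3 alone.

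Outside the Hoxa5 to Hoxa10 block, Hox expression was sparse. Of 5 other Hoxa genes measured, Hoxa3 was above background on all arrays (6.57, 6.57 and 5.50), Hoxa2 on 2 (5.97, 5.45 and 4.27), Hoxa11 on 2 (5.82, 4.44 and 8.05), and Hoxa4 and Hoxa13 on none. Of 22 Hoxb, Hoxc and Hoxd genes, 19 were not above background on any array. The exceptions were Hoxc9 on all arrays (5.70, 5.68 and 5.82), Hoxb4 in replicate 1 (6.23) and Hoxb13 in replicate 3 (5.42). Hoxc9 and Hoxb13 lay close to the background levels of 5.36, 5.23 and 5.33, so their expression is uncertain. The same holds for Hoxa3 in replicate 3, Hoxa2 in replicate 2 and Hoxa11 in replicate 1.

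The genes of the MLL and DOT1L complexes, which write and read histone marks at MLL targets, differed little. Of 19 measured, 18 were above background on all 3 arrays, and 2 of these varied by at least 1 log2 unit. The 18 include Mllt1, whose tied value of 6.72 on every array is no measure of agreement. Kmt2a stood at 7.55 ± 0.14, Dot1l, the H3K79 methyltransferase, at 7.33 ± 0.11, Men1 (menin) at 6.85 ± 0.21 and Psip1 at 8.93 ± 0.19 (SD, n = 3). The 2 that varied were Mllt6, at 6.69, 5.49 and 6.39, and Afdn, the mouse gene of the fusion partner, at 7.24, 5.68 and 7.68 (Entrez gene 17356), which was 3.44-fold lower in replicate 2 than in the others. These probe sets were designed for the mouse genes, and whether they detect the fusion transcript is not known from the table. Among 11 Polycomb genes measured, 9 were above background on at least 1 array and 0 varied by 1 log2 unit.

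The second question was how the 3 leukemias differed in their whole expression profile. Replicate 3 stood apart from the others in 1031 genes, 438 higher and 593 lower, against 141 in replicate 1 (110 higher, 31 lower) and 111 in replicate 2 (43 higher, 68 lower). In all, 1988 of 10562 genes (18.8%) varied by at least 1 log2 unit, and 522 by at least 2, while the median range over all genes was 0.46. Without replicate 3 the count of varying genes was 332. Separate probe sets of the same gene named the same replicate as highest in 68.8% of 3674 genes with at least 2 probe sets above background on all arrays, and in 81.6% of the 554 that varied, where chance gives 33.3% if each array is highest equally often. If 1 array is highest more often, as may hold with replicate 3 standing apart, chance gives a larger share.

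Neutrophil genes were much lower in replicate 3. All 15 measured neutrophil maturation genes were lower in replicate 3 than the mean of the other 2, and 13 were set apart there, with a list median of -3.41 (percentile 0). Lactoferrin (Ltf), a secondary granule protein, was at 13.02, 13.07 and 6.31 (106-fold lower). Fcnb was 71.0-fold, Mmp9 35.3-fold, Lcn2 10.6-fold and Ngp 10.4-fold lower, and Lrg1 was at least 29.4-fold lower. Camp, the cathelicidin gene, was at 14.23, 14.39 and 10.72. Pglyrp1, a further granule protein, was at least 86.5-fold lower. Primary granule genes, which are transcribed earlier in the lineage, differed by less than 1 log2 unit between the leukemias: Mpo (myeloperoxidase) stood at 13.85 ± 0.25, Elane (neutrophil elastase) at 12.59 ± 0.21, Prtn3 at 14.05 ± 0.11 and Ctsg at 13.74 ± 0.25 (SD, n = 3). Mpo, Prtn3 and Ctsg lay near the array maxima, as did Ngp, Camp and Lcn2 in replicates 1 and 2, and differences there may be compressed and folds too small. Gfi1, a list member that encodes a transcription factor and not a granule protein, lay farther below the maxima, at 11.24 ± 0.29 (SD, n = 3). The exception among 9 was Nkg7, a granule protein better known from lymphocytes, at 10.85, 11.44 and 7.22.

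Monocyte and macrophage markers were also lower in replicate 3, with 10 of 14 set apart and a median of -1.68 (percentile 0). Csf1r, the receptor for macrophage colony-stimulating factor, was at 11.77, 10.64 and 9.20, and the chemokine receptor Ccr2 at 9.09, 9.07 and 6.51. Stem and progenitor markers had a median of -2.25 (percentile 0), or -2.12 with values raised to the background level, and 5 of the 8 above background were set apart. Cd34 was at 8.01, 8.69 and 3.52 (at least 8.11-fold lower), the ETS factor Erg at 8.26, 8.61 and 3.23 (at least 8.59-fold lower), Sox4 at 10.55, 10.48 and 6.74 (13.7-fold lower) and Cd48 at 10.09, 9.90 and 6.70 (9.81-fold lower). The stem cell factor receptor Kit was 2.32-fold lower, and Flt3 was similar at 6.38 ± 0.26 (SD, n = 3). With replicate 3 left out, replicate 1 minus replicate 2 had a median of -0.029 over the neutrophil list, 0.031 over the progenitor list and 0.15 over the monocyte list.

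**Figure D2:**
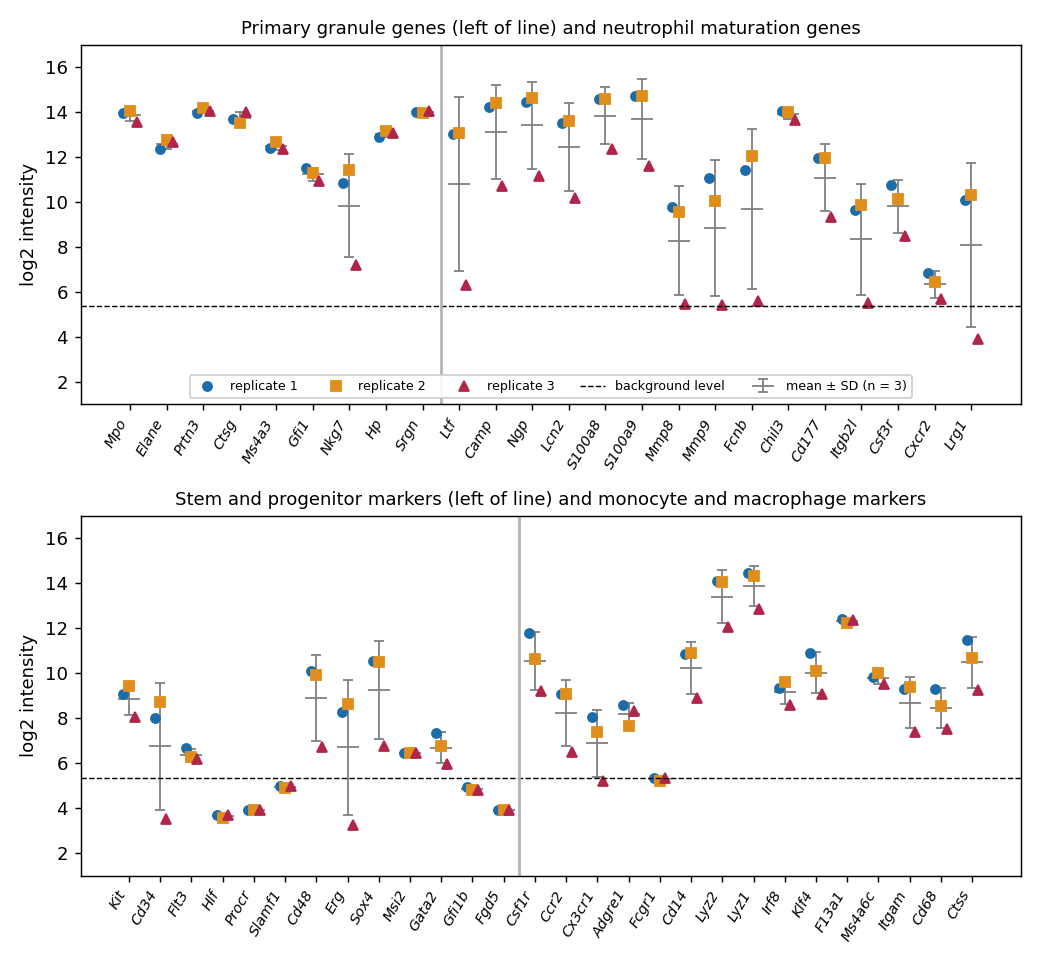
Log2 intensity (vertical axis) of primary granule and neutrophil maturation genes (upper panel) and of stem and progenitor and monocyte and macrophage markers (lower panel) in replicates 1, 2 and 3; grey bars are the mean ± SD over 3 arrays and the dashed line is the highest background level. Primary granule genes other than Nkg7 coincide, while Ltf, Fcnb, Lrg1, Cd34, Erg and Sox4 are far lower in replicate 3.

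The genes farthest above the others in replicate 3 were Tcf24 (at least 61.0-fold), Rnase2a (at least 31.3-fold), Cobll1 (at least 54.2-fold), Mid1 (at least 54.1-fold), Elavl2 (at least 18.8-fold), Gstm2 (at least 10.5-fold), the coagulation factor gene F7 (at least 31.2-fold) and Scin (at least 16.4-fold). All 8 were not above background in replicates 1 and 2. For Cobll1 and Mid1 the remaining probe sets were not above background on any array, while 3 of the 5 probe sets of Elavl2 were above background in replicate 3 alone. The genes farthest below were Dsp, which encodes desmoplakin (at least 37.5-fold), Mecom, Ltf, Pglyrp1, Myl10 (at least 24.2-fold), Lrg1, Hspa1a (at least 61.8-fold) and Fcnb. Interferon response genes were higher in replicate 3, with a median of 0.54 (percentile 99.7) and 5 of 11 set apart (0.93 and percentile 99.98 without replicate 2), among them Rtp4 (at least 4.93-fold), Bst2 (2.92-fold), Ifi27l2a (2.83-fold) and Usp18 (at least 2.17-fold). Ifit1 and Ifit3 were not above background on any array. In the Ras and cytokine signalling list, which had no shift as a whole, the MAP kinase phosphatase Dusp6 was 10.7-fold and Socs3 4.38-fold lower in replicate 3, while Spry2 was 4.76-fold and the cytokine receptor chain Csf2rb 2.60-fold higher.

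Replicate 1 differed in cell cycle, antigen presentation and immediate early genes. All 18 DNA replication genes and all 17 mitosis genes were lower in replicate 1 than the mean of the other 2, with medians of -0.70 and -0.63 (percentile 0 for both). Cdc6, a replication licensing factor, was 2.53-fold lower and was the single replication gene set apart there. The replication list was also higher in replicate 3 (median 0.50, percentile 99.99), with 17 of 18 members above the mean of the other 2 and Ung 2.45-fold higher. Without replicate 1 that median was 0.26 (percentile 98.4). The mitosis shift depended on replicate 2, without which it was -0.23 (percentile 15.2). The MHC class II genes H2-Aa (3.85-fold), H2-Eb1 (3.43-fold), H2-Ab1 (3.03-fold) and the invariant chain Cd74 (3.08-fold) were higher in replicate 1, and the dendritic cell and MHC class II list had a median of 1.02 (percentile 99.99). The 95% interval of that list over genes ran from -0.11 to 1.78, with 7 members higher and 2 lower. T cell receptor components Cd3d (3.23-fold) and Cd3g (at least 3.67-fold) were higher, Cd3e and Cd4 were at 6.07 ± 0.36 and 6.21 ± 0.06 (SD, n = 3), and the T and NK list had a median of 0.45 (percentile 99.94), or 0.36 with values raised to the background level. That T and NK call was lost with the stricter background (median 0.11, percentile 89.6) and with the mean of probe sets (median 0.11, percentile 94.2). B cell markers had a median of 0.33 in replicate 1 (percentile 99.57), a call also lost with the stricter background (percentile 98.5) and without replicate 2 (percentile 98.7).

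Immediate early genes, which respond within minutes to stimulation or handling, had a median of 0.53 in replicate 1 (percentile 100), with Junb (2.55-fold), Egr1 (2.90-fold) and Btg2 (2.72-fold) among 4 of 13 set apart. The inducible heat shock gene Hspa1b was at 13.85, 11.82 and 10.14, and its near-identical copy Hspa1a at 12.24, 10.32 and 4.41, and signal can be shared between this pair. The heat shock list as a whole was not set apart in replicate 1 (median 0.05, percentile 91.4, 8 higher and 4 lower). Replicate 1 also had the highest signal from added control transcripts, with medians of 0.39, -0.40 and 0.02 log2 units from the 3-array mean for the poly-A controls in replicates 1, 2 and 3, and of 0.33, -0.33 and -0.03 for the hybridization controls. The 18S ribosomal RNA probe sets lay at 0.63, -0.08 and -0.59. The Gapdh 3′ probe set exceeded the 5′ probe set by 0.45, 0.17 and 0.16 log2 units, and for beta-actin by 0.90, 0.62 and 0.97. The genes farthest above in replicate 1 were Sp110 (8.80-fold), Tdrd9 (at least 4.90-fold), Col19a1 (at least 2.73-fold), Ly6k (7.21-fold), Gabbr1 (5.55-fold), Stfa2l1 (at least 9.96-fold), Fabp4 (at least 3.39-fold) and cyclin D2 (Ccnd2, 5.63-fold). Those farthest below were Kyat3 (at least 3.71-fold), Slc16a4 (at least 1.32-fold), Alox5 (2.72-fold), Tcf19 (2.55-fold), Ctbs (2.60-fold), Hs2st1 (2.87-fold), Akr1c13 (at least 4.58-fold) and Gstcd (2.93-fold). Akr1c13, at 5.17, 6.43 and 8.68, differed more between replicates 2 and 3 than between 1 and 2.

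Replicate 2 had the highest mitosis genes, with all 17 above the mean of the other 2 and a median of 0.83 (percentile 100). Top2a was at 10.65, 11.73 and 10.89, Mki67 at 11.55, 12.23 and 11.51, and Cenpf was 2.76-fold and Ube2c 2.32-fold higher than in the others. The 8 genes farthest below in replicate 2 were above background in the other replicates and not in this one. Hpgd, a prostaglandin-degrading enzyme, was at 9.74, 4.06 and 9.08 (at least 18.1-fold lower) and Afap1 at 8.75, 3.87 and 9.95 (at least 17.3-fold lower), followed by Slc15a2 (at least 6.31-fold), Rhoj (at least 5.71-fold), Lhfp (at least 6.26-fold), Colec12 (at least 3.55-fold), Fnbp1l (at least 5.72-fold) and Epha7 (at least 13.1-fold). In Rhoj (6.25, 3.35 and 9.24), Lhfp (6.01, 3.18 and 9.76), Fnbp1l (6.85, 4.17 and 8.65) and Epha7 (6.77, 4.36 and 11.13), replicate 1 lay well below replicate 3. The high values of replicate 3 raise these folds, and replicate 2 was less far below replicate 1. Ripk4 (at least 1.69-fold), Tesc (at least 3.85-fold), Ccnf (2.87-fold), Depdc1b (2.84-fold) and Lzts1 (at least 2.80-fold) were among the 8 farthest above. Resident macrophage markers had a median of 0.98 in replicate 2 (percentile 100), which rested on signal near background. With values raised to the background level it was 0.12 (percentile 96.0) and no longer set apart. Heat shock genes had a median of -0.28 in replicate 2 (percentile 0.05), and -0.19 (percentile 9.06) without replicate 1.

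Across the 24 lists and 3 replicates, 32 of 72 shifts lay outside the range from percentile 1 to percentile 99. For lists of genes drawn at random, 1.44 would. Genes of 1 list that vary together leave that range more often, so 1.44 is too low a yardstick for these lists. A list far lower in replicate 3 counts as higher in the other 2, so these are not 32 separate differences. Lists inside that range in every replicate were the MLL and DOT1L complexes, Polycomb, primary granule, erythroid, eosinophil, basophil and mast cell, stromal, Ras and cytokine, p53 target, Bcl2 family, hypoxia and glycolysis, and ribosomal protein genes. None of the 11 measured ribosomal protein genes varied by 1 log2 unit. Megakaryocyte and platelet genes, with 4 of 10 above background, were too few for a percentile. Markers of other marrow cells were present in part. Genes above background on at least 1 array were 10 of 13 T and NK genes, 9 of 17 B cell genes, 7 of 13 stromal genes, 6 of 14 erythroid genes and 5 of 11 eosinophil, basophil and mast cell genes. Alas2 and Gata1 were among the 8 erythroid genes not above background on any array. The B cell genes Cd79a, Pax5 and Ebf1 were not above background, whereas Cd79b stood at 7.64 ± 0.25 (SD, n = 3), Ms4a1 at 7.98, 7.18 and 6.76, and Mzb1 at 9.13, 8.09 and 9.23. The platelet genes Pf4, Ppbp and Gp1bb and the stromal collagens Col1a1, Col1a2 and Col3a1 were not above background on any array, and Cxcl12 was above it in replicate 3 alone (6.12).

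**Figure D3:**
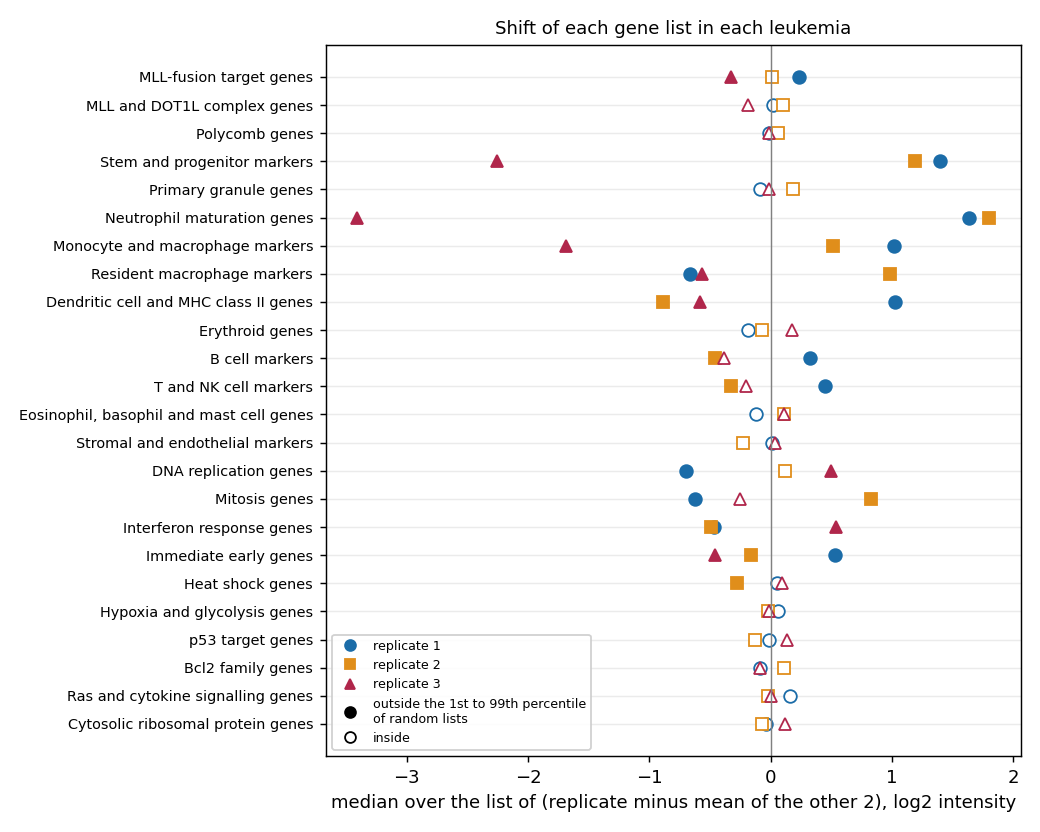
Median over each gene list (rows) of the log2 difference between a replicate and the mean of the other 2 (horizontal axis); filled symbols lie outside percentiles 1 to 99 of 10000 matched random lists. Replicate 3 lies at -3.41 for neutrophil maturation genes and -2.25 for stem and progenitor markers, and at -0.02 for primary granule genes.

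A run of neighbouring genes was lower in replicate 1, found after 4 of the 8 genes farthest below in that replicate (Kyat3, Ctbs, Hs2st1 and Gstcd) were seen to lie near each other on chromosome 3. Among 9558 genes in the scan, the lowest window of 25 neighbours in replicate 1 had a median of -0.88, below the lowest of 1000 permuted gene orders (-0.55). The run reached from Hadh to Zzz3 and held 49 genes above background on all 3 arrays, with a median of -0.86 (95% interval from -0.97 to -0.68 by bootstrap over genes, which are not independent). Replicate 1 was lowest in 43 of the 49. Zzz3 is the last gene of the chromosome with a full window and its window was still below the permuted bound, so the end of the run was not found. The run held 43 genes, from Aimp1 to Fubp1, with windows of 15, and 37, from Hadh to Znhit6, with windows of 50. Members included Tet2, a DNA demethylase and tumour suppressor of myeloid cells (7.89, 8.75 and 8.98), the translation initiation factor Eif4e (8.93, 10.08 and 10.42), the NF-kappaB adaptor Bcl10 (9.14, 10.32 and 9.84) and the histone gene H2az1 (11.95, 12.92 and 12.89), all named after their values were seen. The remaining 395 genes of the chromosome had a median of -0.08. The highest window in replicate 1 (0.43) also passed its permuted bound (0.39), on chromosome 6 from Ccdc126 to Mpp6, with a median of 0.08 over 3 genes. With windows of 15 genes, 8 immunoglobulin kappa genes on chromosome 6, from Igk to Igkv6-14, were also lower in replicate 2 (median -1.15), which windows of 25 or 50 did not show. With windows of 50, parts of the chromosome 3 run were higher in replicate 2 (Lamtor3 to Znhit6, 19 genes, median 0.31) and in replicate 3 (Dnajb14 to Selenof, 17 genes, median 0.53), the counterpart of its low value in replicate 1.

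**Figure D4:**
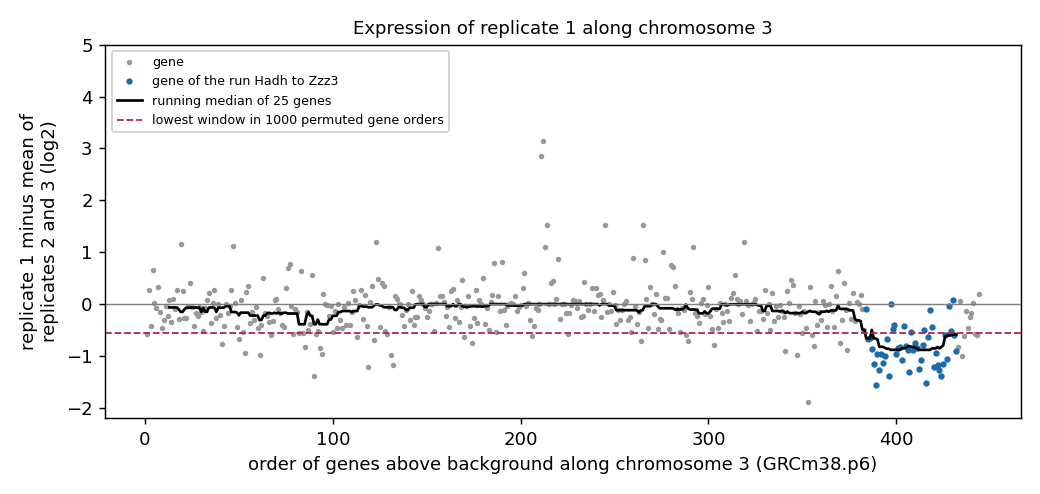
Log2 difference between replicate 1 and the mean of replicates 2 and 3 (vertical axis) for genes above background in their order along chromosome 3 (horizontal axis); the black line is the running median of 25 genes and the dashed line is the lowest window of 1000 permuted gene orders. The 49 genes from Hadh to Zzz3, in blue, have a median of -0.86, and the other 395 a median of -0.08.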

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

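The neighbour run's alternatives and the raising of values to background were chosen after seeing the data; the others were planned. No test of a difference between mice was possible with 1 array each, and signal near background limits what can be seen of dim genes. No paired analysis was possible because there is 1 group. Total counts of genes and lists stayed within 1.5 times under the stricter background, the mean of probe sets, both rescalings and no filter, but the split by direction moved more: genes lower in replicate 1 fell from 31 to 13 and those lower in replicate 2 from 68 to 44 with the mean of probe sets, and lowess scaling left 21 lower in replicate 1. A threshold of 1.5 log2 units left 900 varying genes and 36, 28 and 523 set apart in replicates 1, 2 and 3, fewer by construction, with 1 of the 36 lower and 2 of the 28 higher. With 1 replicate left out, set apart means a difference between 2 arrays: counts ranged from 332 to 1506 for varying genes, 332 to 1506 for replicate 1, 332 to 1416 for replicate 2 and 1416 to 1506 for replicate 3, the low ends of the first 3 being without replicate 3. Genes above background then ranged from 9644 to 9880, lists set apart from 14 to 22, and the mean correlation between arrays from 0.969 to 0.991. That mean was 0.977 over all probe sets and 0.928 over those above background. Agreement between probe sets on the highest array was 81.6% in varying genes and 73.0% to 85.4% with 1 array left out. Chance gives 33.3% with 3 arrays that are highest equally often and a larger share with 2, so these values are not comparable as they stand. List shifts changed sign when a replicate was left out in 6 cases, given here as the lowest and highest value: immediate early genes in replicate 2 (-0.41 to 0.023), MHC class II genes in replicate 3 (-1.26 to 0.21), neutrophil maturation (-0.029 to 3.36) and interferon (-0.93 to 0.13) genes in replicate 1, and progenitor (-0.031 to 2.29) and monocyte (-0.15 to 1.44) genes in replicate 2. Each shift is a contrast with both other arrays, so leaving out the one that differs most can turn it. Counted once per list shift and alternative, another 37 outcomes crossed a percentile bound and 516 stayed the same, so 1 list shift can count more than once. Values raised to background gave 3 of the 37, which left 29 of 72 list shifts set apart. The distance of a named gene from the nearest array kept its size of at least 1 log2 unit in 235 alternatives. It fell below that size, in the same direction, in 5, all with the mean of probe sets. Leaving out a replicate cannot lower this distance, and median centring hardly moved the arrays, so those alternatives decide nothing here. With the mean of probe sets 43 distances kept that size, and with lowess scaling 48 did. Mean levels were less stable: 94 moved and 166 did not with the mean of probe sets, and 21 moved with lowess scaling. The chromosome 3 run ranged from -0.88 with windows of 15 genes to -0.80 with lowess scaling.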

Other observations

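The tests that weigh explanations below, the neighbour scan and the raising of values to background were chosen after the values were seen, whereas the lowess scaling and the gene lists were planned. Gzma, a granzyme, was 5.32-fold and Thy1 4.34-fold higher in replicate 3, and Vcam1, an adhesion molecule, 11.2-fold higher, while Nkg7 was 15.2-fold lower. Of the T cell genes there, Cd3d (6.16), Cd3e (5.87) and Cd4 (6.25) were above background and Cd3g was not. The T and NK list as a whole was not set apart in replicate 3 (median -0.20, percentile 3.38, 4 higher and 6 lower). Among granulocyte genes of other kinds, the eosinophil protein gene Prg2 was 3.95-fold higher in replicate 1, Siglecf 2.98-fold higher in replicate 2, and the basophil protease gene Mcpt8 2.64-fold lower in replicate 2, and Epx and Cpa3 were not above background on any array. The scavenger receptor Cd163 was at 6.96, 5.91 and 3.27 in replicates 1, 2 and 3.

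The chromosome 3 run is a hypothesis worth following up: replicate 1 may carry fewer copies of this segment, Tet2 included, than replicates 2 and 3. Chance order of genes is argued against, since the lowest of 1000 permuted orders reached -0.55 and the lowest observed window -0.88. Noise of single probe sets is argued against too, since the other 32 probe sets of the same genes had a median of -0.78 and all 32 lay below 0. The median over the run was -0.86, with quartiles at -1.13 and -0.59 and replicates 2 and 3 differing by -0.06. A copy number difference would give such a one-sided shift, but the size of the shift does not decide. Whole marrow may mix cells with and without such a difference, and then no whole-copy ratio need be met. The run was found in the same values and its criteria were set afterwards, so meeting them is not separate support. Loss, gain in the other 2 and a donor strain difference stay open without DNA or a normal control. Neither 3 copies against 2 (-0.58) nor 1 against 2 (a fall of 1 log2 unit) lay inside the interval over genes (-0.97 to -0.68). Those ratios hold only if every cell carries the difference, so they argue against neither.

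Replicate 3 combined low neutrophil, monocyte and progenitor genes with primary granule genes, Nkg7 aside, near the level of the others, some of them close to the array maxima. A leftover intensity-dependent trend is argued against, since 1042 genes were set apart in replicate 3 after lowess scaling against 1031 before. The deposited arrays already had nearly equal quantiles, so lowess scaling had little to remove. It therefore cannot weigh array brightness before normalization, and the 18S ribosomal RNA signal of replicate 3 was the lowest of the 3 (-0.59). A smaller share of mature neutrophils could lower Ltf and Camp but would not lower Cd34, Erg or Sox4, and the progenitor list had a median of -2.25 (-2.12, with an interval over genes from -3.29 to -0.32, with values raised to the background level). For the neutrophil genes themselves (median -3.41), fewer neutrophils in the sample and leukemic cells halted earlier cannot be told apart, because both lower the list. The cells were thawed before extraction, so the sample need not hold neutrophils in the share of the marrow. Beyond cell composition no biological explanation was tested, since the design names no difference between the mice.

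Replicate 1 had low replication genes and high MHC class II and T cell genes. Dilution of the leukemia by other cells would lower the MLL-fusion targets as far as the replication genes (median -0.69 with values raised to the background level). The median of these targets was 0.23 (percentile 99.82, set apart), or 0.09 (percentile 92.9) without replicate 2. This does not decide, because 10 members were higher and 7 lower, with an SD over members of 1.10, so dilution stays open as a cause of the low replication genes. A few more lymphocytes and antigen-presenting cells may account for Cd3d, Cd3g and H2-Aa. The T and NK median of 0.45 (0.36, from -0.02 to 1.06, with values raised to background) does not decide this, because expression within the leukemic cells would give the same.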
